A study of Arabidopsis thaliana with 4 samples.

How the data were processed

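RNA was sequenced from whole Arabidopsis thaliana seedlings of 2 lines of the Columbia accession (Col-0), named SALK Col-0 and Another Col-0 in the labels, with 2 biological replicates of each. Plants were 2 weeks old, grown in soil at 22 °C in long days, and frozen in liquid nitrogen at harvest, per the labels' protocols. Libraries were made with a TruSeq RNA V2 kit, a kit that by its standard protocol does not mark the strand of a transcript, and read as single ends of 101 nt on a HiSeq sequencer. Nothing in the labels says whether the replicates of a line came from separate trays or days, so p-values of single models measure the spread between these libraries.

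The authors deposited 1 table of FPKM values (fragments scaled by transcript length in kilobases and by the mapped fragments of the library) for 36251 gene models in each of the 4 libraries, with lower and upper limits and a status beside each value, per the file headers. TopHat, Cufflinks and Cuffdiff and the TAIR10 genome build are named in the submitters' processing notes, with no versions or roles given in the sources used here. The models are merged ones that carry transcript start groups and the annotated transcripts they hold, and 4129 models hold no annotated transcript. The deposited upper limits of the FPKM values were used only to see whether a value lies between its own limits; 1.09% to 1.37% of the values above 0 in a library did not. The lower limits are a further deposited column of other values, read for the same purpose. In 301 rows of chloroplast and mitochondrial genes the annotation fields are displaced, and there the gene was read from the field that holds its identifier. A failed or too deep estimate in any library removed 19 models. Gene symbols came from a RefSeq table of the TAIR10.1 assembly, which matched 32801 of 33542 gene identifiers. Coordinates are those of the deposited table, counted from 1. A model that names several genes pools their reads, and models that overlap or lie antisense to each other may share reads where strand is not marked.

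Read totals are not in the table. The sum of FPKM was 1762918 and 1076877 in replicates 1 and 2 of SALK Col-0, and 1590250 and 1228118 in those of Another Col-0. The lowest step of FPKM times model length, roughly the worth of 1 read, would correspond to about 33800000 and 44700000 reads in SALK Col-0 and 33400000 and 45400000 in Another Col-0, in the same order. This is a hint only, because Cufflinks does not count whole reads, and no counting interval is given.

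Values were taken as log2(FPKM + 1), so folds on that scale understate changes of low genes. Models with a mean of at least 1 FPKM over the 4 libraries were tested with limma 3.58.1 (R 4.3.3): a linear model with the line as its term, moderated with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are Another Col-0 minus SALK Col-0. The model had 2 residual degrees of freedom. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so p-values come from limma's pooled spread. The replicate number was not a term in the model. Values within each replicate number (1 library of each line) are given beside the pooled ones.

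The gene lists, the rule for named genes and most alternatives, listed below by choice, were fixed before the data were examined. The lists had 604 entries, and 1 entry whose identifier carries another name in the reference was left out. Together with the chloroplast-encoded and mitochondrion-encoded genes they gave 28 lists with at least 3 measured models. The lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 28 lists, and members were also counted by p adjusted over the list alone. At the preset correlation camera takes its spread across models, which are not replicates, so its p-values do not measure the spread between libraries. A list of transposable element genes was not run, because the reference table used here carries no such class. Neighbouring calls were set against 10000 random placements. Genes detected in 1 line had at least 1 FPKM in both of its libraries and under 0.05 in both of the other.

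The text names by this rule models past the threshold with the largest differences (filled up to 5 per direction with the largest non-overlapping differences that did not pass), up to 4 members per list by smallest p, FLC and QQS, genes of neighbouring runs, and up to 10 genes detected in 1 line. Genes chosen after their values were seen are named as such. The alternatives fixed at that point covered the pseudocount, the filter, the scaling, the trend, library weights, the replicate block, each library left out, a minimum span of 300 nt and a threshold of 0.10. Restriction to annotated models, with and without the block, to annotated models alone in their bundle, or to nuclear models, and keeping failed estimates, were chosen after seeing the data. A bundle is a stretch of the genome whose models overlap or adjoin and share an interval in the table.

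The tests were checked on simulated values made from these libraries, with 50 models changed at each size. The changed models were drawn from those with higher means, and spreads were shuffled among models. Recovery among low models was thus not checked. Among 20634 models, the line model recovered 0% of changes of 1 in log2, 26% of changes of 2 and 58% of changes of 4. Among the 18432 annotated models it recovered 16%, 52% and 94%. The share of exonic 101-nt windows of each named gene that occur once in the reference genome was counted by exact match on both strands. Figures were drawn with matplotlib 3.10.9.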

Results

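The data are FPKM values of gene models in whole 2-week-old seedlings of 2 Arabidopsis Col-0 lines that were reproduced separately, SALK Col-0 and Another Col-0, with 2 biological replicates of each. The design asks which transcripts differ between lines of the same accession that have been kept apart. Between 22495 and 22822 annotated models had a value above 0 in each library, and the median of annotated models with at least 1 FPKM lay between 15.2 and 15.6 FPKM. Read totals are not in the table, and the counting error behind each value was not estimated here. The deposited limits of each value were used only as a range check. Values are given below as the mean ± SD of 2 libraries.

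Some genes had well-replicated higher values in Another Col-0, beside short models listed at 0 in a line, some with larger differences, that are described further on. Those named here are examples from 146 annotated models at least 2-fold higher in both replicate pairs, where 30 were lower. Apart from QQS, the genes of this paragraph were chosen after their values were seen. QQS (AT3G30720, chromosome 3, 12348972 to 12349973), an orphan gene that affects the partition of carbon between starch and protein and is known to occur in methylated and unmethylated states, had 6.70 ± 0.891 FPKM in SALK Col-0 and 144 ± 11.5 FPKM in Another Col-0, a 21.5-fold ratio. HEI10 (AT1G53490, chromosome 1, 19963267 to 19970359), which encodes an E3 ligase that promotes meiotic crossovers, had 3.61 ± 0.103 against 20.95 ± 0.098 FPKM. A model spanning the MATE transporter genes AT2G04050, AT2G04066 and AT2G04070 (chromosome 2, 1337223 to 1355860) had 1.05 ± 0.0836 against 7.43 ± 0.0167 FPKM. AT5G44585 (chromosome 5, 17984587 to 17985598) was 6.24-fold higher, at 8.76 ± 0.483 against 54.6 ± 3.98 FPKM. XTR6 (AT4G25810), a xyloglucan endotransglycosylase of the cell wall, had 30.4 ± 0.448 against 111 ± 3.54 FPKM, and AT3G50800 had 3.81 ± 0.157 against 15 ± 0.327 FPKM.

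In the test over all 20634 models with a mean of at least 1 FPKM, 0 models were higher and 0 lower at an adjusted p under 0.05, and none were called at 2-fold either (limma, smallest adjusted p = 0.199). This test had no term for the replicate number, so a difference between numbers that both lines share counted as spread within a line. With such a term many models were called, as given further on. Without it, at an unadjusted p under 0.05 there were 3439 models, where 1032 would be expected by chance. Over the 18432 annotated models alone, a restriction chosen after the data were seen, 10 models were higher and 1 lower in Another Col-0, all at least 2-fold. The log2 differences of the genes above in that fit were 4.24 ± 0.125 (SE) for QQS, 2.25 ± 0.066 for HEI10, 2.04 ± 0.074 for the AT2G04050 model, 2.51 ± 0.093 for AT5G44585, 1.83 ± 0.077 for XTR6 and 1.73 ± 0.070 for AT3G50800. Their adjusted p-values in limma lay between 0.0333 and 0.0478, and each was higher in both replicate pairs. The pseudogene AT5G35935, also chosen after its values were seen, passed too, at 5.37 ± 0.0505 against 18.9 ± 0.275 FPKM. The other 4 calls were short models listed at 0 in both libraries of a line, described below. With any single library left out, the annotated models gave between 0 and 5 calls per direction, and all 11 genes kept their direction, but 0 of them were still called without SALK Col-0 replicate 1, 1 without SALK Col-0 replicate 2 and 2 without either Another Col-0 library. Among the 11836 annotated models that are alone in their bundle, 139 were higher and 57 lower. Of the 11 calls, 5 could be tested there, and all 5 passed. HEI10, the AT2G04050 model, AT5G44585 and AT5G35935 lie in bundles of 3, 5, 3 and 3 models. Their values may depend on how reads were divided among those models.

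**Figure D1:**
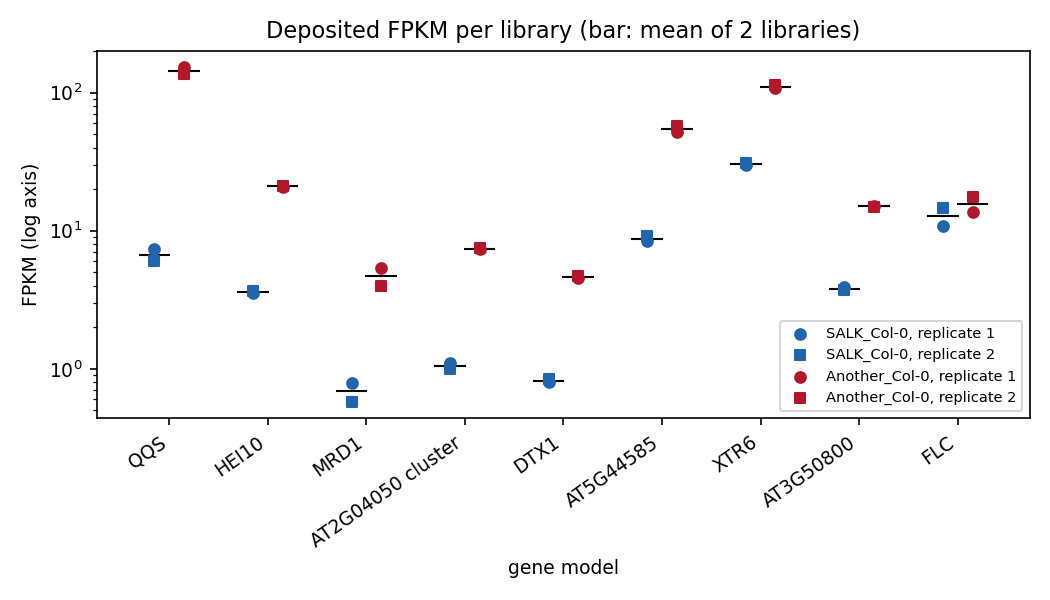
Deposited FPKM of 9 gene models in each library (log axis); blue and red points are the SALK Col-0 and Another Col-0 libraries, circles and squares replicates 1 and 2, and bars the mean of 2 libraries. QQS lies at 6.07 to 7.33 FPKM in SALK Col-0 and at 136 to 152 FPKM in Another Col-0, while the FLC values of the lines overlap.

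Since libraries of the same replicate number were closely correlated, the line difference was also read within each number. Among annotated models, 228 were at least 2-fold higher and 113 at least 2-fold lower in Another Col-0 in the replicate 1 pair, and 204 and 62 in the replicate 2 pair. In both pairs 146 were higher and 30 lower, where 2.52 and 0.380 would be expected from independent pairs, and 5 moved in opposite directions. The line difference of QQS was 4.2 in the replicate 1 pair and 4.28 in the replicate 2 pair, and that of HEI10 was 2.27 and 2.23. The values of the lines did not overlap in 9677 annotated models (52.5%), where 4 exchangeable libraries would give 33.3% by chance, a condition that the correlation within replicate numbers does not meet. FLC (AT5G10140), the repressor of flowering, had 12.7 ± 2.61 FPKM in SALK Col-0 and 15.6 ± 2.66 in Another Col-0, and its difference of 0.28 ± 0.213 (0.31 and 0.25 in the replicate 1 and 2 pairs, and 0.09 without SALK Col-0 replicate 1 to 0.48 without SALK Col-0 replicate 2) did not pass (limma, adjusted p = 0.617).

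**Figure D2:**
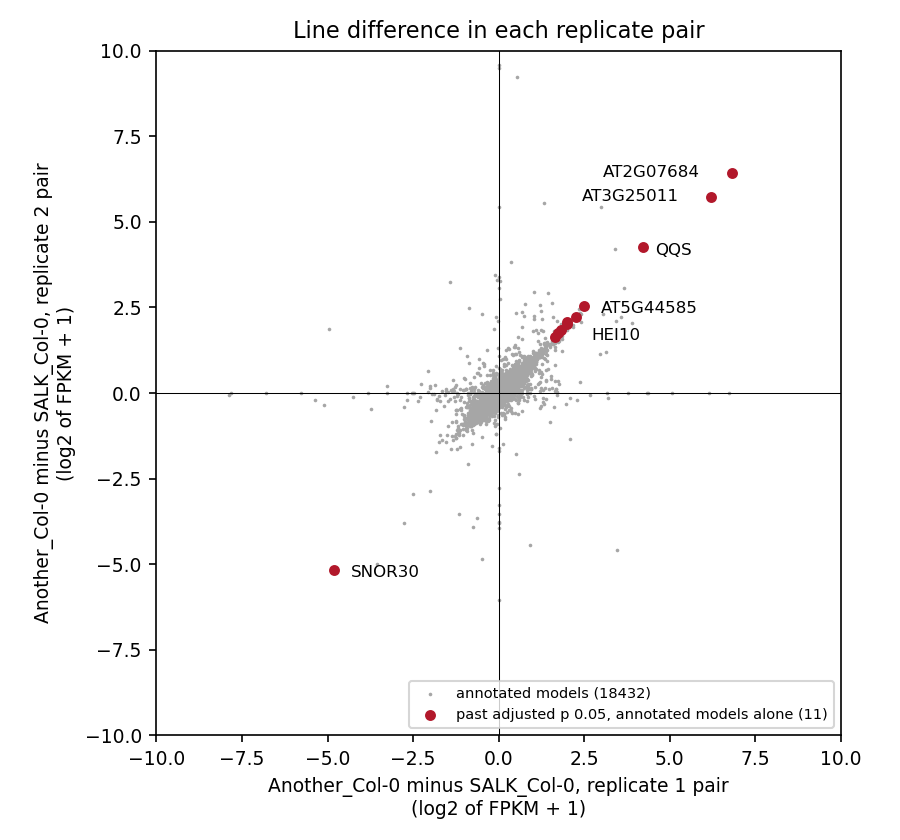
Difference between the lines in log2(FPKM + 1) for 18432 annotated models, in the replicate 1 pair (horizontal) and the replicate 2 pair (vertical); red points are the 11 models past the threshold among annotated models. QQS lies at 4.2 and 4.28, and SNOR30 at -4.80 and -5.18.

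Genes written down as early responders to touch, wounding and elicitors were mostly higher in Another Col-0. Of 29 measured members, 19 were higher, 1 was lower and 9 did not pass when adjusted over the list alone, and 0 passed over all models. ZAT10, a zinc finger repressor of stress responses, had 17.2 ± 0.535 FPKM in SALK Col-0 and 48.6 ± 3.81 in Another Col-0. WRKY18, a regulator of defence, had 11.7 ± 0.439 against 27.9 ± 0.501 FPKM, and the ethylene response factor gene ERF105 had 27.6 ± 0.970 against 61.1 ± 6.15 FPKM. BAP1, an inhibitor of cell death, had 2.06 ± 0.0678 against 5.37 ± 0.290 FPKM. The single lower member was WRKY33, a regulator of camalexin synthesis, at 92.8 ± 5.11 against 68.7 ± 3.803 FPKM, named after its value was seen. The list median was 0.52 (0.47 in the replicate 1 pair and 0.53 in the replicate 2 pair), with 26 of 29 members positive in both pairs (camera, adjusted p = 1.64e-09; adjusted p = 0.453 with an estimated correlation). Leaving out any library kept the sign of the median, between 0.42 and 0.56, and left 0 members past the threshold over the list alone.

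Chloroplast-encoded models also had higher FPKM in Another Col-0 as a list, and a ribosomal RNA gene had a higher mean. The 34 measured chloroplast models had a median of 1.11 (0.75 and 1.69 in the replicate 1 and 2 pairs; camera, adjusted p = 3.34e-06; adjusted p = 0.512 with an estimated correlation). The sum of FPKM over all chloroplast-encoded models was 2055 and 4503 in replicates 1 and 2 of SALK Col-0. In those of Another Col-0 it was 3645 and 8843, so the sums of the lines overlapped. In both lines the sum was higher in replicate 2 than in replicate 1. Adjusted over the list alone 0 members passed, and 12 were higher when annotated models alone were fitted. The photosystem II gene psbZ (ATCG00300) had 12.4 ± 2.75 against 67.4 ± 11.5 FPKM, and psbK (ATCG00070) had 58.9 ± 9.46 against 110 ± 3.92 FPKM. The 31 mitochondrion-encoded models had a median of 0.20 and did not pass (camera, adjusted p = 0.185). The ribosomal RNA gene AT3G41768, named after its values were seen, had 99.0 ± 12.3 against 279 ± 5.36 FPKM, and AT2G01021 was listed at 970.2, 20488, 910.1 and 96257 FPKM in replicates 1 and 2 of SALK Col-0 and of Another Col-0. The difference of AT2G01021, 1.07, turned to -1.13 without SALK Col-0 replicate 1, -2.29 without Another Col-0 replicate 2 and -0.04 after quantile normalization.

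Morning genes of the circadian clock were lower in Another Col-0. Of 11 members, 0 were higher, 5 lower and 6 did not pass when adjusted over the list alone, and 10 were lower when annotated models alone were fitted. The pseudo-response regulator genes PRR9 and PRR7 had 2.73 ± 0.0659 against 1.09 ± 0.126 FPKM and 165 ± 3.89 against 126 ± 0.0728 FPKM. LNK1, a coactivator of clock genes, had 20.0 ± 1.78 against 11.6 ± 0.824 FPKM, and RVE4, a MYB-like activator of evening genes, had 134 ± 0.391 against 99.2 ± 2.34 FPKM. The list median was -0.46 (-0.41 and -0.52 in the replicate 1 and 2 pairs), with 10 of 11 members negative in both pairs (camera, adjusted p = 3.32e-06; adjusted p = 0.453 with an estimated correlation). Without any single library 0 members passed, and 10 stayed negative. The 11 evening genes had a median of 0.02, with 0 past the threshold (camera, adjusted p = 0.468), although its medians within the replicate 1 and 2 pairs were -0.11 and -0.04. Its member with the smallest p, PRR5, had a difference of -0.45 ± 0.077.

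Nitrate assimilation genes were higher in Another Col-0: 3 of 4 passed over the list alone. With the replicate number as a term in the model, the list did not pass (camera, adjusted p = 0.0635). The nitrate reductase genes NIA1 and NIA2 had 132 ± 3.42 against 203 ± 13.0 FPKM and 395 ± 21.3 against 599.7 ± 2.72 FPKM, and the nitrite reductase gene NIR1 had 102 ± 0.155 against 137 ± 6.003 FPKM. The transceptor gene NRT1.1 had 53.5 ± 1.53 against 55.2 ± 3.97 FPKM. The list median was 0.51 (0.51 and 0.50 in the replicate 1 and 2 pairs; camera, adjusted p = 0.0121; adjusted p = 0.511 with an estimated correlation), and 3 members passed without Another Col-0 replicate 1 but 0 without any other library. The list of loci known to carry epialleles also passed on the higher side (6 models, median 0.26; camera, adjusted p = 0.0197; adjusted p = 0.511 with an estimated correlation), but QQS was its single member past the threshold, and the tryptophan synthesis gene PAI1 had a difference of 0.28 ± 0.064. Without SALK Col-0 replicate 1 that list did not pass (adjusted p = 0.0538).

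A further 5 lists passed camera on the lower side with small medians. In the abscisic acid, drought and cold list, 1 of 26 members was higher and 2 lower over the list alone: the cold response regulator CBF2 had 4.58 ± 0.0727 against 8.64 ± 0.131 FPKM, while the abscisic acid synthesis gene NCED3 had 6.91 ± 0.344 against 3.61 ± 0.127 FPKM and the proline synthesis gene P5CS1 had 66.7 ± 0.315 against 42.8 ± 1.95 FPKM. The list median was -0.17 (camera, adjusted p = 0.00153; adjusted p = 0.512 with an estimated correlation), and 0 members passed without any single library. Cell division genes (26 models, median -0.18, adjusted p = 0.00249), iron deficiency and storage genes (18 models, median -0.20, adjusted p = 0.0196), DNA methylation and RNA silencing genes (38 models, median -0.08, adjusted p = 0.0196) and flavonoid genes (11 models, median -0.34, adjusted p = 0.0233) had 0 members past the threshold over the list alone. With an estimated correlation the iron and flavonoid lists had an adjusted p = 0.511 and the cell division and silencing lists an adjusted p = 0.512. Fitting annotated models alone gave 2 higher and 4 lower members in the abscisic acid list and 1 higher and 5 lower in the flavonoid list. The DNA demethylase gene ROS1 had a difference of -0.38 ± 0.073, the chromomethylase gene CMT2 one of -0.32 ± 0.059, and the chalcone synthase gene CHS one of -0.41 ± 0.104. Without SALK Col-0 replicate 1 the cell division list did not pass (median -0.07, adjusted p = 0.0689), nor did the iron list without Another Col-0 replicate 2 (adjusted p = 0.121), nor the silencing list without SALK Col-0 replicate 2 (adjusted p = 0.0936) or Another Col-0 replicate 1 (median -0.02, adjusted p = 0.166). Quantile normalization ended the calls of the flavonoid list (adjusted p = 0.0844) and of the silencing list (adjusted p = 0.0508).

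**Figure D3:**
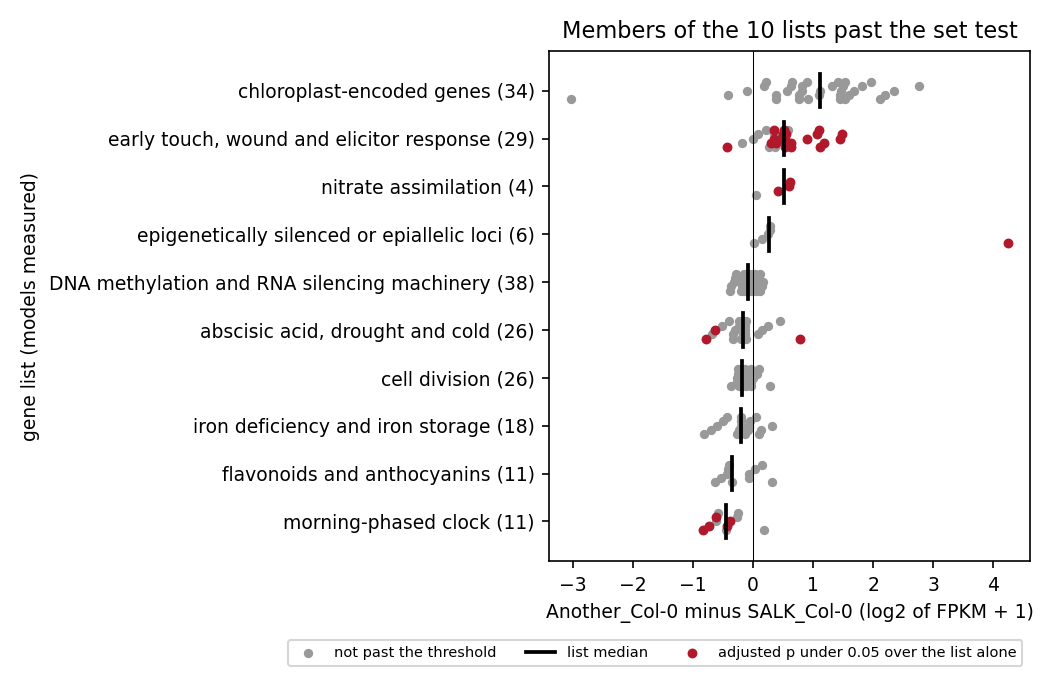
Difference between the lines in log2(FPKM + 1) for each measured member (points) of the 10 lists past the set test, with red points past an adjusted p of 0.05 over the list alone and a black bar at each list median. The touch, wound and elicitor list has 19 members higher, the morning clock list 5 lower, and the chloroplast-encoded list a median of 1.11.

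The marker lists for other organs did not pass as lists. Of the 3 flower markers measured, the floral homeotic genes PI and SEP3 were higher over the list alone, at 3.03 ± 0.249 against 9.02 ± 0.850 FPKM and 14.7 ± 3.503 against 32.9 ± 3.97 FPKM, and SHP1 had a difference of -0.04 ± 0.148 (list median 1.13; camera, adjusted p = 0.0847). The seed storage protein gene CRA1 was lower, at 7.08 ± 0.299 against 2.16 ± 0.168 FPKM (5 seed markers, median -0.21; camera, adjusted p = 0.0712). Of 21 root markers, 2 were higher (the thalianol pathway gene THAD and the aquaporin gene TIP2;3) and 1 lower (the peroxidase gene PER64), with a median of 0.02 (camera, adjusted p = 0.823). In the flowering time list 0 of 18 members passed over the list alone (median -0.17), and the list did not pass (camera, adjusted p = 0.388). FT, which encodes the mobile flowering signal, had 1.00 ± 0.0606 against 3.35 ± 0.390 FPKM (limma, adjusted p = 0.0665 over the list alone). The difference of FT was 1.176 and 1.055 in the replicate 1 and 2 pairs. FT passed over the list alone when annotated models alone were fitted. Without either Another Col-0 library 1 flower marker passed, without SALK Col-0 replicate 1 no seed marker passed, and without any single library no root marker passed, with root medians between -0.10 and 0.07.

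Defence and metabolic lists held members that went both ways. For indole glucosinolates and camalexin, 5 of 12 members were higher and 1 lower over the list alone (median 0.10; camera, adjusted p = 0.0847), with the indole glucosinolate hydroxylase gene CYP81F2 at 10.6 ± 0.502 against 24.6 ± 1.13 FPKM. For jasmonate, 3 of 29 were higher and 3 lower (median -0.06; adjusted p = 0.389), with the vegetative storage protein gene VSP2 at 26.7 ± 0.0967 against 14.97 ± 0.538 FPKM. In the senescence list, 2 of 12 were higher and 2 lower (median 0.11; adjusted p = 0.823), with SAG21 at 493.6 ± 27.4 against 1503 ± 107 FPKM and the senescence regulator NAP at 40.2 ± 6.86 against 18.4 ± 1.22 FPKM. In the salicylic acid list, 1 of 17 was higher, the AZI1 model that also holds EARLI1, and 1 lower, WRKY70 (median 0.11; adjusted p = 0.223). The early auxin list had 0 of 23 higher and 1 lower, SAUR19 (median -0.20; adjusted p = 0.0558). Among annotated models it passed camera (adjusted p = 0.0488; adjusted p = 0.578 with an estimated correlation), with 1 member higher and 5 lower, and the jasmonate list had 4 higher and 5 lower. Without any single library these counts were 0, except for 1 higher and 1 lower senescence gene without SALK Col-0 replicate 2, and the medians lay between -0.16 and 0.04 for jasmonate, 0.05 and 0.23 for senescence, -0.31 and -0.10 for auxin and 0.12 and 0.20 for the indole list.

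The remaining lists had 0 members past the threshold over the list alone and did not pass camera. These were nuclear photosynthesis (47 models, median -0.06), sulfur starvation (11, -0.06), carbon starvation (15, 0.13), NLR immune receptors (26, 0.02), heat shock (21, -0.04), phosphate starvation (16, 0.03) and aliphatic glucosinolates (22, 0.02), with adjusted p-values between 0.189 and 0.823. Fitting annotated models alone gave 3 higher heat shock genes, 2 higher mitochondrion-encoded genes, 1 higher flowering time gene, 2 lower seed markers, and 1 higher and 1 lower evening clock gene. For the evening clock, NLR, aliphatic glucosinolate and root lists the median was above 0 while camera, which sets a list against all other models, pointed lower; for heat shock the mean was 0.04.

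A few genes were detected in a single line by the deposited values, most of them short. By the fixed rule 13 genes were detected in Another Col-0 and 6 in SALK Col-0, and 14 of these 19 span under 300 nt. AT2G07684 (chromosome 2, 3262235 to 3262345) was listed at 0 in both SALK Col-0 libraries and at 111 and 84.8 FPKM in Another Col-0; 0% of its 101-nt windows occur once in the reference, since each has a copy in the mitochondrial genome. AT3G25011 (chromosome 3, 9113168 to 9113281) was listed at 0 in both SALK Col-0 libraries and at 72.8 and 52.3 FPKM in Another Col-0, and AT5G56865 at 0 against 2.98 and 3.04 FPKM. The small nucleolar RNA gene SNOR30 (AT5G51174, chromosome 5, 20795936 to 20796051) was listed at 26.8 and 35.3 FPKM in SALK Col-0 and at 0 in both Another Col-0 libraries. These 4 are the short models among the 11 calls above. FPKM is scaled by length, so a few reads can give a high value in such short models. AT3G25011 lies in a bundle of 11 models and SNOR30 in a bundle of 2. A listed 0 there may reflect reads given to another model rather than absence. The unnamed genes AT2G11271, AT5G13181, AT2G20784 and AT1G35183 were listed at 0 in SALK Col-0 and AT1G35242 and AT4G09649 at 0 in Another Col-0, none past the threshold over all models or over annotated models. Among annotated models alone in their bundle, 5 of 7 tested genes detected in Another Col-0 and 3 of 4 detected in SALK Col-0 passed, with AT5G13181, AT4G09649 and AT1G35242 among them (limma, adjusted p = 0.0274, 0.0274 and 0.0451).

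Other large differences varied widely between the replicates of a line. The model of AT1G74453 and AT1G74456 was listed at 11.9 and 0 FPKM in SALK Col-0 and at 17.5 and 598 FPKM in Another Col-0, and the model without annotated transcript at AT5G55400 at 0.00 and 132 against 182 and 281 FPKM. In the lower direction, the model of MIR825 and AT2G26220 was listed at 11.6 and 788 against 10.5 and 0.664 FPKM, AT5G10336 at 327 and 35.9 against 27.1 and 0.166 FPKM (differences of -3.54 and -4.99 in the replicate 1 and 2 pairs), and LOG1 (AT2G28305) at 7603 and 37.8 against 31.4 and 36.3 FPKM. Their SE lay between 2.27 and 3.11 in log2, and none passed (limma, adjusted p between 0.460 and 0.630). AT5G10336 passed when the replicate number was a term in the model (limma, adjusted p = 0.0340).

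Few differing genes were neighbours, but at an unadjusted threshold there were more such pairs than random placement gave on average. With 0 calls in the test over all models there were 0 neighbouring pairs. Among 140 nuclear models at least 2-fold apart with an unadjusted p under 0.01, 4 neighbouring pairs went the same way, where random placement gave 0.675 on average (one-sided permutation p = 0.0053 over 10000 placements). These were HEI10 with MRD1, a methionine-responsive gene that overlaps it on the opposite strand (0.686 ± 0.154 against 4.67 ± 0.986 FPKM), DTX1, a MATE transporter gene, with the AT2G04050 model (DTX1 at 0.816 ± 0.0284 against 4.63 ± 0.107 FPKM), AT5G44575 with AT5G44578, and a pair of models in the mitochondrial insertion of chromosome 2 (3468962 to 3479682). MRD1 and DTX1 did not pass over all models or among annotated models (limma, adjusted p = 0.0794 and 0.0535 among the latter). Counting annotated models in separate bundles left 2 pairs against 0.827 at random (one-sided permutation p = 0.201). The densest 500 kb window, chromosome 5 from 17500001 to 18000000, held 7 of the 140 models, where the mean was 0.588: AT5G44575, AT5G44578, AT5G44585, AT5G44568 and FLA13 (AT5G44130) had higher means in Another Col-0, and the seed gene CRA1 and the defensin gene PDF1.2 (AT5G44420) lower ones. The pairs and this window were singled out after their values were seen.

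By correlation, libraries of the same replicate number resembled each other more than libraries of the same line. Over all tested models, Pearson's r across models, which are not independent replicates, was 0.711 and 0.735 between the replicates of SALK Col-0 and Another Col-0, and 0.978 and 0.976 between the lines within replicate numbers 1 and 2. Among annotated models it was 0.960 and 0.965 against 0.978 and 0.979, and the median absolute log2 difference was 0.148 and 0.134 between replicates of a line against 0.170 and 0.165 between the lines within a number. Of 2199 nuclear models without an annotated transcript, 2083 (94.7%) differed at least 2-fold between the replicate numbers in both lines, against 1.67% of 18370 annotated ones.

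**Figure D4:**
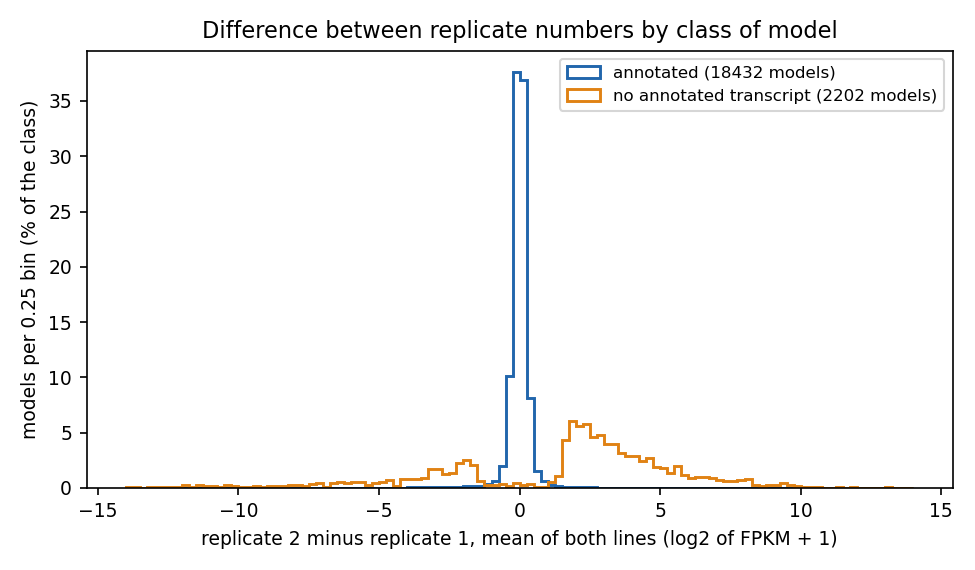
Difference between replicate 2 and replicate 1 in log2(FPKM + 1), averaged over both lines, as the percentage of each class of model per bin of 0.25. The annotated models (blue) centre on 0, while the models without an annotated transcript (orange) lie on both sides of it.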

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

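The alternatives restricted to annotated models, nuclear models or models alone in their bundle, those keeping failed estimates, and the minimum span for genes detected in 1 line were chosen after the results were seen. Over all models the counts of 0 higher and 0 lower stayed 0 in the alternatives of pseudocount, filter, scaling, trend, weights, span, threshold and left-out library, while the replicate block gave 2951 higher and 1673 lower (149 and 40 at 2-fold). Annotated models alone gave 10 and 1 (10 and 1 at 2-fold), with the block 4896 and 3335 (165 and 40), and annotated models alone in their bundle 139 and 57 (66 and 15). The block assumes that libraries with the same number belong together, which the labels do not state; the correlation across models of the 2 replicate differences, 1 per line, was 0.953 over all models, 0.789 over annotated ones and 0.749 over those alone in their bundle. Without the block, a difference between replicate numbers that both lines share counts as spread within a line. In the simulated values, the block recovered 0%, 28% and 50% of changes of 1, 2 and 4 in log2 over all models. The fit without it recovered 0%, 26% and 58%. Among annotated models the block recovered 60%, 64% and 78%, against 16%, 52% and 94% without it. How much of the changes in calls the shared difference accounts for in these libraries was not tested.

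Of the 4 lists higher and 6 lower, camera with an estimated correlation called 0 and 0, on 2 residual degrees of freedom, and fry over all lists called 4 higher and 3 lower: it left out the chloroplast list and 4 of the 6 lower ones (all but the morning clock and flavonoid lists), and called the indole and seed lists besides. The correlation that camera estimated was 0.0121 for the touch list and -0.011 for the morning clock list, against the preset 0.01. A higher correlation thus does not account for the lost calls of these lists in that mode. Among annotated models camera at the preset correlation called 4 higher and 7 lower. Quantile normalization ended the calls of the silencing list (adjusted p = 0.0508, with 0.0936 to 0.512 in the other alternatives that ended it) and of the flavonoid list (0.0844, and 0.511 with an estimated correlation), and the block ended that of the nitrate list (0.0635, and 0.0724 among annotated models). In 95 of the alternative results the called lists kept their direction and call, in 24 the call was lost, and in 0 the direction changed. Named genes kept direction and side of the threshold in 336, passed in 51 (FLC under the block, adjusted p = 0.0410, and 0.0139 among annotated models, against 0.421 to 0.873 in its other alternatives) and reversed in 3, all for AT2G01021: 1.07 became -0.04 under quantile normalization and lay between -2.29 and 4.43 without any 1 library, where the lone library of a line is assumed to vary like those of the other line.

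Against 0 neighbouring pairs, the unadjusted threshold gave 4, the block 665 (555 at random, permutation p = 0.0001, the smallest 10000 placements can give), that threshold among annotated models in other bundles 2, and the block with a 2-fold limit as well among those models 3. Genes detected in 1 line, 13 and 6, became 30 and 10 with the wider limits and 4 and 0 at a span of at least 300 nt. The span rule also dropped the mitochondrial gene ATMG00280, detected in SALK Col-0, because no coordinates were read for it. The median absolute differences of 0.163, 0.165 and 0.254 (same line, same number, neither) became 0.182, 0.184 and 0.283 with a pseudocount of 0.1, and 0.141 for the same line and 0.221 for neither among annotated models. The alternative with 1 member per run of adjacent paralogs was not run, as there were 0 calls to thin. Read totals are not in the table, and no limit was computed from the rough hint of depth.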

Other observations

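The tests of opposite strands, depth, root share, hour of harvest, handling and a duplicated segment were chosen after the result was seen. Of the annotated models at least 2-fold apart in both replicate pairs, 121 of 146 higher and 27 of 30 lower in Another Col-0 belonged to none of the lists, and the examples here were chosen after their values were seen. Among the models higher in Another Col-0 were the glutathione transferase model GSTF7 and GSTF6 (51.9 ± 7.15 against 183 ± 26.5 FPKM), the deadenylase gene CAF1a (11.4 ± 1.03 against 39.1 ± 2.13 FPKM), the lipase gene PLA2A (5.75 ± 0.127 against 18.5 ± 1.11 FPKM), the ethylene synthesis gene ACS11 (4.52 ± 0.249 against 13.2 ± 0.655 FPKM) and the inositol oxygenase gene MIOX2 (123.5 ± 18.4 against 319 ± 52.9 FPKM). Among those lower were MBP1, which encodes a myrosinase-binding protein (17.65 ± 1.195 against 5.62 ± 0.0566 FPKM), NCED4, of carotenoid cleavage (64.2 ± 4.66 against 25.6 ± 2.78 FPKM), the wax synthesis gene CER1 (25.9 ± 3.42 against 10.1 ± 1.05 FPKM) and PRE1, a regulator of cell elongation (28.5 ± 1.44 against 11.7 ± 0.447 FPKM). The model of FRO6 and FRO7 was also lower, at 71.4 ± 0.225 against 31.0 ± 0.221 FPKM. None of these passed over all models or among annotated models.

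Models without an annotated transcript differed at least 2-fold between the replicate numbers in both lines in 2083 of 2199 cases, 1543 of them higher in replicate 2. Different expression of the overlapped genes is argued against by their median absolute log2 difference of 0.212 between the numbers, which is above the 0.131 of other annotated models but far under the 2-fold that sets the pattern. Replicate 2 may be deeper (about 44700000 and 45400000 reads against 33800000 and 33400000, a rough hint), but the 25.9% that were higher in replicate 1 argue against depth as the whole cause. Models higher in replicate 2 had a median of 0 FPKM in replicate 1 and 9.39 in replicate 2. Those higher in replicate 1 had 9.87 in replicate 1 and 0 in replicate 2. FPKM is scaled by the mapped fragments of the library, so these medians also argue against a depth difference of that size. Of those higher in replicate 2, 87.6% overlapped annotated genes on the opposite strand alone, against 23.0% of those higher in replicate 1, so the replicate numbers may differ in how reads were given a strand. The design names no group for the number, and no other biological explanation was tested.

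Early touch, wound and elicitor genes had a median of 0.517 between the lines. A larger share of root in the Another Col-0 seedlings is argued against by the root marker median of 0.015. The evening clock median of 0.023 beside a morning median of -0.46 leaves the hour of harvest open, and with no untouched plants handling before freezing cannot be told apart from a difference between the lines, which may also account for these genes and was not tested. Chloroplast-encoded transcripts (median 1.11), the ribosomal RNA gene AT3G41768 (2.82-fold) and the flower markers PI and SEP3 had higher means in the same line. The summed chloroplast FPKM overlapped between the lines, at 4503 in SALK Col-0 replicate 2 and 3645 in Another Col-0 replicate 1.

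QQS, HEI10 and the AT2G04050 model were higher in Another Col-0 among annotated models, and their neighbours MRD1 and DTX1 had higher means without passing. Reads shared with identical copies are argued against by the 90.6% or more of their 101-nt exonic windows that occur once in the reference. The medians of the 10 nearest annotated models, the farthest from 0 being -0.062 at QQS, argue only against a duplication of most of them. At QQS those models lie between 11859948 and 12593527 and range from -1.12 to 0.78. A duplication of these genes alone or with a few neighbours was not tested. HEI10 and MRD1 overlap on opposite strands, so reads of 1 may count for the other. A heritable difference between the lines in sequence or DNA methylation at these loci may account for the values, a hypothesis that expression values alone cannot test.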
